A study of Caenorhabditis elegans with 2 samples.

How the data were processed

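The series measured where the GFP-tagged protein MADF-5 lay on the genome of whole Caenorhabditis elegans L4 larvae aged 48 hours. Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing (ChIP-seq) in 2 samples, which the labels number as biological replicates 1 and 2 of 1 group. Per the labels, the worms carried the tagged gene at its own locus, were synchronised by starvation after bleaching, and their chromatin was sonicated. A possible control experiment is named in the labels and was not analysed here, so no value below has a background measured in the same way.

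The starting point was 8 deposited peak lists on assembly ce11, without headers. Each replicate had a ranked list and a thresholded list, and the series had 2 of each kind made from both replicates. One thresholded list of the series is called conservative in its file record. The ranked list that holds each of its peaks with the same score was taken as its partner, and the other pair was matched the same way. Per the deposited file records, the lists derive from alignments to ce11 and from further files whose content the records do not state. The series lists derive from the alignments of both replicates. The inputs between which each IDR was computed, the peak caller, the aligner and their versions are not given in the sources used here. The column meanings follow the standard peak-list layouts and the values.

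The signal of a peak is the authors' own value per peak, deposited on a scale that no record states, and it was used to rank and describe peaks. The score is the authors' scaled irreproducible discovery rate (IDR), the estimated share of peaks at a given rank that do not recur between the inputs. The deposited −log10 values are the authors' q-value of the peak caller and their global IDR. The largest IDR in the conservative list was 0.01, and its lowest score was 830. Caller q-values in the deposited conservative list had a median of 0.179, and 374 of 1124 peaks had a q-value of at most 0.1. In each ranked list of the series, 2 columns appear to give the signal in each input. These 4 columns carry no sample name and were not used. The signal per replicate was taken instead from the peak of that replicate's own ranked list with the largest overlap. No read counts are in the lists analysed here, so depth is unknown and no interval for sequencing depth was made. The 95% intervals of shares are exact Clopper-Pearson intervals over peaks or genes. They treat peaks or genes as independent, and cover neither depth nor the variation between worms.

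The reference was assembly WBcel235, the same sequence as ce11, with Ensembl annotation release 115. All peaks lay within the lengths of its chromosomes. The 6 nuclear chromosomes hold 46890 annotated genes, of which 44112 have a symbol and 19973 are protein-coding. Transfer RNA isotypes came from the RefSeq annotation of the same assembly and were matched by gene identifier for 607 of 612 tRNA genes.

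The main peak set was the conservative list, because it derives from both replicates. A gene was called bound when a summit lay from 1000 bp upstream to 200 bp downstream of the start of any of its transcripts. Shares of summits were compared with shares of the genome by 2-sided exact binomial tests. Gene lists (32, fixed as symbol patterns) and 11 biotypes were compared with other genes by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was a call. The background was every nuclear gene with a symbol for lists and every nuclear gene for biotypes. Windows of 101 bp at summits were compared with 10 windows each at the same offset from starts of genes without a summit within 2000 bp. Summits over 1000 bp from a gene start were matched to random windows. The leading 6-mer was found on chromosomes I, III and V and tested on II, IV and X. Permutation tests used 100000 resamples, the overlap of replicates 1000 random placements, and label rotation 10000 rotations. These tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the genes at the 20 strongest conservative peaks, the genes of the MADF family, the 4 bound members with the highest signal of each called list, the 3 strongest peaks over 1000 bp from a gene start, and the 3 strongest peaks of each replicate's list without overlap in the other's.

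The functions were tested on simulated data with 1124 summits per draw. This was done only after a first run on the deposited lists, and all values given here come from the later run. With random summits, 8 of 100 draws called any of the 32 gene lists, and the X, gene start and centre tests called 4, 1 and 4 of 100 draws. A list with summits placed at 40% of its members was called in 100 of 100 draws. A 6-mer placed in 30% of the windows was found in 10 of 10 draws, and the held-out test called 0 of 10 draws without one. Random summits gave calls for protein-coding genes in 36 of 100 draws, piRNA genes in 24 and ncRNA genes in 11, for a reason that was not tested. The p-values of those 3 biotypes are therefore too small. tRNA genes were called in 1 of 100 draws, snoRNA genes in 0 and snRNA genes in 0.

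Alternatives covered the other peak lists, each replicate's list alone, stricter IDR and q-value limits, the peaks with the highest signal, other start windows, backgrounds, window sizes and word lengths. The alternative with the nearest gene start only gave each summit to 1 gene, whose start could lie up to 1000 bp away on either side. An alternative limit of an IDR of at most 0.01 equals the deposited threshold and moved nothing. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.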

Results

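Binding of MADF-5, a protein with a MADF domain (a DNA-binding domain related to that of Myb), was mapped by anti-GFP ChIP-seq in L4 larvae, the last larval stage of C. elegans. The data were 2 biological replicates of 1 group, described here through the authors' peak lists on assembly ce11. The conservative list, which derives from both replicates, held 1124 peaks, and the other thresholded list of the series held 1145. Replicate 1 alone had 337 thresholded peaks and replicate 2 had 325, so the larger was 1.04 times the smaller. Conservative peaks had a median width of 276 bp and together covered 0.307% of the genome. Their median signal, in the authors' unit, was 86.3, with quartiles of 75.7 and 108.

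The replicates named partly the same sites. Of the 337 thresholded peaks of replicate 1, 184 (54.6%, 95% interval 49.1% to 60.002%) overlapped a thresholded peak of replicate 2 by at least 1 bp. Random placement of the second list gave 0.176% on average and 1.19% at most over 1000 placements. In the conservative list, 303 peaks overlapped the list of replicate 1, 299 that of replicate 2, and 182 both, while 704 (62.6%) overlapped neither. Signal in the 2 replicates was compared across the 1105 conservative peaks that each replicate's ranked list contained. Pearson's r of log2 signal was 0.616 and Spearman's rho was 0.372, each with a permutation p of 1e-05, the smallest that 100000 resamples can give. Peaks are not independent replicates, and these were chosen partly for their concordance. Over the 33453 peaks of replicate 1's ranked list with a partner in replicate 2's, rho was 0.259.

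**Figure D1:**
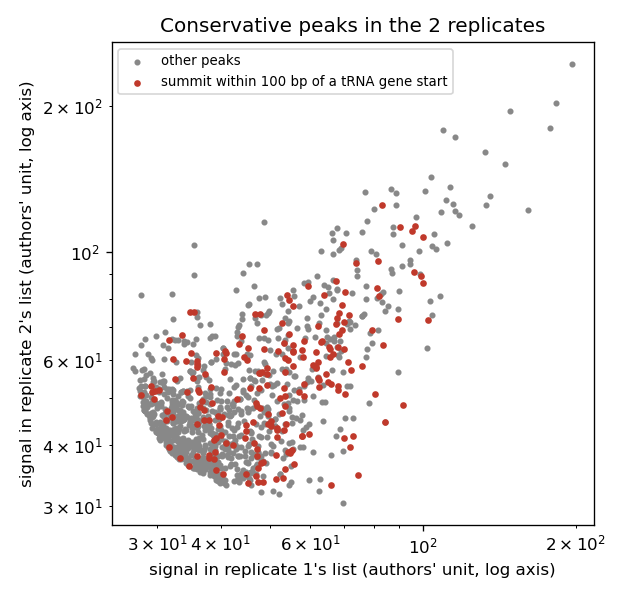
Each point is a conservative peak, with the signal (authors' unit, log axes) of the overlapping peak in replicate 1's ranked list on the x axis and in replicate 2's on the y axis. Red points have a summit within 100 bp of a tRNA gene start. Over the 1105 peaks with both values, Spearman's rho was 0.372.

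The 20 strongest conservative peaks were of mixed kinds. Ribosomal protein genes, small nucleolar RNA (snoRNA) genes, the gene for the RNA of RNase P and collagen genes were among their neighbours, a grouping made after the peaks were seen and without a test. The strongest of all, at III:3867487-3867660, had a signal of 444 (197 in replicate 1 and 244 in replicate 2). Its summit lay 283 bp upstream of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. A peak at IV:4749992-4750134 with a signal of 266 lay 292 bp upstream of rpl-20 and 170 bp upstream of Y17G9B.5. Another, at IV:654848-654922 with a signal of 247, lay 344 bp upstream of rpl-15. The start window of K11H12.8 and those of the snoRNA genes K11H12.12 and K11H12.13 also held the rpl-15 summit. The peak at V:12303544-12303699 with a signal of 365 had its summit 15 bp inside the snoRNA gene C51F7.4 and 94 bp upstream of C51F7.3, both within the span of frm-7. Peaks with signals of 283 and 262 lay 73 bp upstream of the snoRNA gene W03C9.9 and 53 bp upstream of the snoRNA gene T03F7.8, the latter also in the window of the ncRNA gene T03F7.14. The peak at I:13463836-13464111, with a signal of 240.95, had its summit 19 bp inside rpr-1, the RNA component of RNase P, which trims tRNA precursors.

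Of the 20 strongest summits, 3 lay in coding exons within cuticle collagen genes, outside any gene start window. Each also lay within the span of a further gene, C34H4.5, ZK1193.2 or ugt-65. They were in col-107 (IV:1549209-1549387, signal 307), col-19 (X:422378-422502, signal 254.7) and col-130 (IV:12427762-12427898, signal 238). Other peaks of this group lay at the starts of protein-coding genes. One with a signal of 307 had its summit 50 bp upstream of tasp-1 and in the window of K01G5.10. Others were 243 bp upstream of mog-4 (signal 300), between the divergent genes F44E5.4 and F44E5.5 (signal 285), 376 bp upstream of eel-1 (signal 238) and 650 bp upstream of rpa-2, in the window of the lincRNA gene M04F3.7 too (signal 245). Peaks at IV:4727969-4728104 and IV:4725528-4725678, with signals of 390 and 348, flanked the pseudogene WBGene00023323, and the latter lay in the window of the ncRNA gene WBGene00195021. A peak with a signal of 232 lay 384 bp upstream of the ncRNA gene C46C2.12. The 3 strongest peaks over 1000 bp from any gene start were in an intron of cmk-1 at IV:1831235-1831510 (signal 250, 3255 bp from the start of ccm-2), downstream of F40E3.3 at I:2639777-2639885 (signal 247) and between genes at X:4209150-4209425 (signal 219, 1803 bp from F20B6.9).

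Of annotated tRNA genes 46.1% (282 of 612, 95% interval 42.1% to 50.1%) had a summit in their start window, against 2.15% of other genes. The share was 21.5 times that of other genes (Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 1.37e-276). The test took genes as independent, although neighbouring tRNA genes can share a summit, so this p may be too small. The summits sat on the genes themselves: the median offset from the start was 15 bp, and 238 of the 282 bound tRNA genes had their summit within 100 bp of it. Of the 1124 peaks, 240 (21.4%) lay within 500 bp of a tRNA gene. Bound tRNA genes spanned the isotypes. Among isotypes with more than 1 gene, histidine had the lowest share (5 of 20) and aspartate the highest (18 of 27, 66.7%), and 0 of 21 isotypes differed from the rest after adjustment. The smallest unadjusted p by Fisher's exact test was 0.00759, for serine. tRNA genes lying within protein-coding genes were bound in 43.8% of cases (127 of 290) and those outside in 48.1% (155 of 322; Fisher's exact test, p = 0.292).

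**Figure D2:**
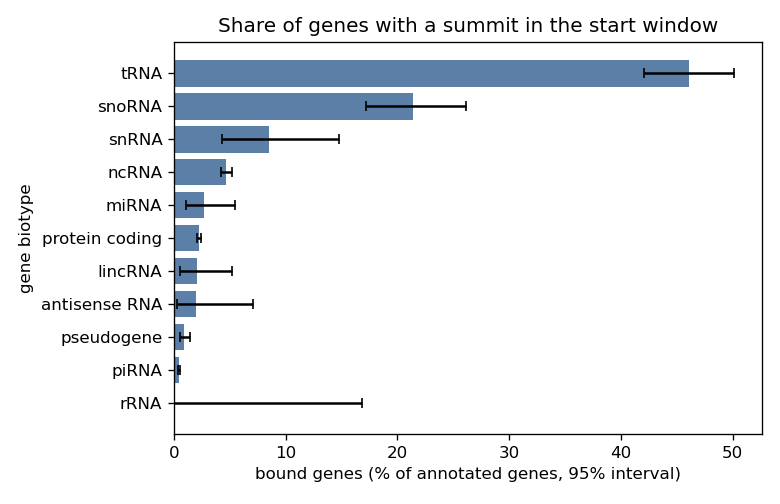
Bars give the percent of annotated nuclear genes of each biotype with a conservative summit in the start window, and error bars are exact 95% intervals. tRNA genes stand at 46.1%, snoRNA genes at 21.4%, snRNA genes at 8.53% and protein-coding genes at 2.23%.

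Genes for snoRNAs, which guide the modification of ribosomal RNA, followed. Of 346, 74 were bound (21.4%, 95% interval 17.2% to 26.1%), 8.29 times the share of other genes (Fisher's exact test, adjusted p = 2.99e-43), a ratio of 15.8 without replicate 1 and 12.2 without replicate 2. Genes for snRNAs, the RNAs of the spliceosome, were bound in 11 of 129 cases (8.53%, Fisher's exact test, adjusted p = 0.0013). Summits at bound snoRNA genes had a median offset of -43.5 bp from the start, negative being upstream (quartiles -114 and -21.2 bp). Those at protein-coding genes had a median of -310 bp, and 87 of 446 lay within 100 bp of the start. Protein-coding genes were bound in 2.23% of cases, piRNA genes in 0.43%, pseudogenes in 0.893% and genes of the ncRNA class in 4.69%. Each differed from other genes by Fisher's exact test, with adjusted p-values of 3.73e-08, 2.09e-131, 4.33e-09 and 4.9e-27. The other genes were bound in 3.08%, 3.83%, 2.81% and 2.33% of cases, so only the ncRNA class lay higher. The genes set against protein-coding genes include the tRNA genes. Among all genes except tRNA genes 2.15% were bound, and protein-coding genes at 2.23% were not below that. Without replicate 1 the ratio went from 3.15 to 5.41 for snRNA genes, and that of piRNA genes, 0.112, was 0.0622 without replicate 1 and 0.0488 without replicate 2. Random summits also gave calls for protein-coding, piRNA and ncRNA genes, in 36, 24 and 11 of 100 draws.

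**Figure D3:**
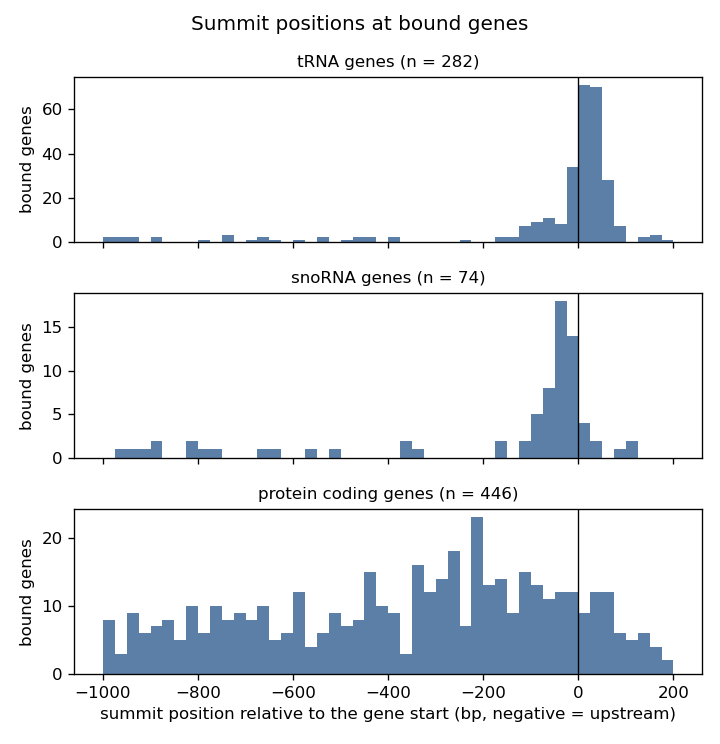
Histograms give the number of bound genes (y axis) by the position of the summit nearest the gene start (x axis, bp, negative upstream, 25 bp bins drawn from 1000 bp upstream). Median positions are 15 bp for tRNA genes, -43.5 bp for snoRNA genes and -310 bp for protein-coding genes.

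Among the 32 gene lists, ribosomal proteins, chaperones and mitochondrial respiration were bound more often than other genes, and chemoreceptors less often. Of 81 ribosomal protein genes 14 were bound (17.3%, 95% interval 9.78% to 27.3%), 7.93 times the share of other genes (Fisher's exact test, adjusted p = 8.84e-08). This ratio was 14.3 without replicate 1 and 17.2 without replicate 2. The 4 with the highest signal were rpl-3, rpl-20, rpl-15 and rpl-35 (signal 178). Of 59 chaperone genes, which encode protein-folding factors, 9 were bound (15.3%, Fisher's exact test, adjusted p = 5.99e-05). They were led by dnj-28 (signal 168), dnj-13 (148), hsp-60 (136) and hsp-1 (122). Of 39 respiration genes 5 were bound (12.8%, Fisher's exact test, adjusted p = 0.0128). They were led by cox-6A (signal 130) and cox-5A (104.1), of cytochrome c oxidase, and by atp-4 (97.7) and atp-5 (96.2), of the ATP synthase. Without replicate 1 the ratio went from 6.96 to 10.8 for chaperones and from 5.83 to 9.71 for respiration. The respiration call was lost when gene labels were rotated along the chromosomes (permutation test, ratio 4.32, adjusted p = 0.0848). By Fisher's exact test it was also lost without replicate 2 (ratio 6.35, adjusted p = 0.256) and at an IDR of at most 0.001 (ratio 7.34, adjusted p = 0.188). The ratios of these last peak sets lay above 5.83, while the sets were smaller (337 and 274 peaks). With the nearest gene start only, the adjusted p of Fisher's exact test was 0.0832 for respiration (ratio 6.13) and 0.0701 for chaperones (ratio 5.41). For summits inside the gene's span, an alternative chosen after the data were seen, ribosomal proteins, chaperones and respiration did not pass (Fisher's exact test, adjusted p = 0.1, 0.116 and 0.744).

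Of 1369 genes matching the chemoreceptor pattern 7 were bound (0.511%, Fisher's exact test, adjusted p = 8.1e-06), and the 4 with the highest signal were sre-23 (184), srpr-2.2 (115), srh-269 (109) and srbc-1 (102). The pattern also takes in 5 srpr genes, which are not chemoreceptor genes and are annotated as ncRNA. Of these 3 were bound, against 4 of the 1364 others. By Fisher's exact test the call was lost without replicate 2 (ratio 0.353 against 0.226, adjusted p = 0.24) and with the nearest gene start only (adjusted p = 0.0724). The other 28 lists did not pass. They include cuticle collagens (5 of 175 bound at their starts), histones (3 of 72), tRNA synthetases (2 of 32), nuclear hormone receptors (3 of 269), molting genes (1 of 48) and heterochronic genes (1 of 9). Cuticle collagens did pass with the nearest gene start only (23 bound, ratio 10.8, Fisher's exact test, adjusted p = 2.35e-15) and with windows from 2000 bp upstream to 500 bp downstream (17 bound, ratio 2.88, Fisher's exact test, adjusted p = 0.00113). The former takes summits up to 1000 bp downstream of the start, against 200 bp in the main window. It therefore changed the window as well as the gene assigned.

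No gene of the MADF family was bound at its start, 0 of 10, with an upper 95% limit of 30.8%, while 1 was bound with the other series list. The nearest conservative summit lay 2774 bp from the start of madf-5 (II:14573615-14576561), at II:14570841 with a signal of 78.4. The start window of madf-5 held 2 peaks of the ranked list, the stronger with a signal of 25.3 and an IDR of 0.423. That of madf-9 (IV:3637079-3640466) held a ranked peak with a signal of 76.0 and an IDR of 0.0118, just outside the limit of 0.01. madf-11 (III:5600381-5603489) was nearest to a summit, which lay 1221 bp from its start and within the gene, at III:5602230 with a signal of 105. Distances for madf-4, madf-9, madf-10, madf-1, madf-3, madf-6, madf-2 and madf-8 ran from 7816 to 87131 bp.

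In the genome as a whole, 62.5% of summits (703 of 1124, 95% interval 59.6% to 65.4%) lay in a gene start window, against 38.6% of the genome (exact binomial test, p = 5.2e-59). For the windows of protein-coding genes alone the share was 34.0% against 26.2% (exact binomial test, p = 9.27e-09), an alternative chosen after the data were seen. Coding exons (10.8% against 16.8%), introns (11.8% against 24.3%) and intergenic sequence (8.81% against 12.8%) held fewer summits than their share of the genome, with adjusted p-values of the exact binomial test of 3.52e-08, 4.7e-25 and 5.34e-05. Coding exons held 6.77% without replicate 1 and 5.04% without replicate 2, and introns 5.85% and 5.93%. The intergenic call ended when the peaks absent from the list were included (13.6%, exact binomial test, adjusted p = 0.588), an alternative chosen after the data were seen. Untranslated regions, noncoding exons and the 500 bp downstream of gene ends did not pass the test. For 3' UTRs (1.69%) fewer summits became a call with the stronger 50% of peaks (0.712%, exact binomial test, adjusted p = 0.0152). The same held at 2 limits chosen after the data were seen, an IDR of at most 0.001 (0%) and a q-value of at most 0.1 (0.535%), with adjusted p-values of the exact binomial test of 0.00705 and 0.0336. The 3' UTR share was 0.615% without replicate 1 and 0.593% without replicate 2, neither a call (exact binomial test, adjusted p = 0.0901 and 0.0638).

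The X chromosome held 252 summits, 22.4% (95% interval 20.01% to 24.97%), against 17.7% of the genome (exact binomial test, p = 5.46e-05, adjusted p = 0.000327). Chromosome V held fewer than its length predicts (16.8% against 20.9%, exact binomial test, adjusted p = 0.00217). X carries 276 of the 612 tRNA genes. Without the peaks within 500 bp of a tRNA gene, 131 of 884 summits (14.8%, 95% interval 12.5% to 17.3%) lay on X, below its share of the genome (exact binomial test, p = 0.0274, adjusted p = 0.164). The same 14.8% lay above X's share of all gene starts, 12.8%, and of protein-coding gene starts, 13.7%, neither past the exact binomial test (p = 0.0872 and 0.327). These alternatives were chosen after the data were seen. On V the share was then 19.1% (exact binomial test, adjusted p = 0.423). tRNA genes on X were bound in 50.4% of cases (139 of 276) and those on the autosomes in 42.6% (143 of 336), which did not pass Fisher's exact test (p = 0.0609). The central 50% of the chromosomes held 49.2% of summits, a share for which the exact binomial test did not pass (p = 0.612). Against the share of gene starts in these parts, 44.9%, the same summits were more frequent (exact binomial test, p = 0.00362). Against that of protein-coding gene starts, 55.3%, they were less frequent (exact binomial test, p = 4.43e-05).

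**Figure D4:**
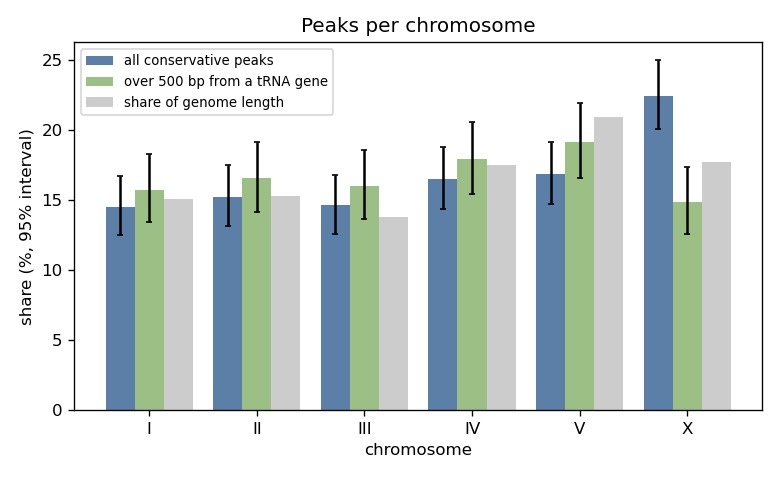
For each chromosome, bars give the percent of all 1124 conservative summits, of the 884 summits over 500 bp from a tRNA gene, and of the genome's length. Error bars are exact 95% intervals. On X the shares are 22.4%, 14.8% and 17.7%.

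Summits lay in GC-rich sequence. The windows at summits had a mean GC content of 49.5% (SD 8.65, n = 1124 windows), against 35.9% (SD 8.68, n = 11238) in matched windows, a difference of 13.6 percentage points (permutation p = 1e-05, the smallest possible). Of 2080 words of 6 bases, 572 were more frequent and 345 less frequent at summits on chromosomes I, III and V. The leading one was AGCGCG (CGCGCT on the other strand), in 9.11% of 516 windows against 1.3% of matched ones. On chromosomes II, IV and X it was in 5.92% of 608 windows against 1.2%, a ratio of 4.93 (Fisher's exact test, p = 1.8e-12). It was not the most enriched word there, as some words found on I, III and V had higher ratios and others lower. CGGCCA (TGGCCG) was in 12.8% of these windows against 1.66%, a ratio of 7.72 (Fisher's exact test, p = 1.27e-35). The ratio of AGCGCG was 9.52 without replicate 1 and 9.41 without replicate 2. With the stronger 50% of peaks the leading word was CGAACC (GGTTCG), with a ratio of 11.01. With windows matched on GC content, 37 words passed on I, III and V, and the ratio of AGCGCG on the other chromosomes was 1.65 (Fisher's exact test, p = 0.00818). Over 500 bp from tRNA genes with the same matching, AGCGCG did not pass (ratio 1.59, Fisher's exact test, p = 0.0609). With all peaks the leading word was then GTTCAA (TTGAAC), with a ratio of 2.12 (Fisher's exact test, p = 6e-08). Over 500 bp from tRNA genes AGCGCG led with and without GC matching, and neither CGAACC nor GTTCAA did. Peaks within 500 bp of a tRNA gene had a higher median signal than the others (102 against 83.0). No separate value is given here for CGAACC or GTTCAA away from tRNA genes, so neither can be read as a sequence preference apart from the tRNA genes. Matching on GC content and distance from tRNA genes were chosen after the data were seen.

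The strongest peaks of one replicate's list without overlap in the other's were at the tRNA genes WBGene00022920 and WBGene00023063 and 337 bp upstream of wip-1 for replicate 1, with signals of 91.5, 84.2 and 89.2. For replicate 2 they were upstream of serp-1.1 (signal 116), iff-2 (103) and tos-1 (94.4). Each of these 6 sites had a weaker peak in the ranked list of the other replicate, with signals from 35.5 to 56.5, and overlapped a conservative peak.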

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

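The 2 tests on occurrence in 1 replicate were chosen after the ranked lists had been seen. In the ranked list that pairs with the conservative list, 93 peaks passed the score minimum of 830 and were absent from the thresholded list. The strongest of them, at X:15810947-15811167, had a signal of 3293, with 1616 in replicate 1 and 1882 in replicate 2, against 444 for the strongest peak kept. They drew attention as a signal in data outside the main peak set, and 12 of the 20 strongest peaks of that score were among them. Of the 93, 66 (71.0%, 95% interval 60.6% to 79.9%) lay between genes. Several absent peaks lay close together, as near Y95D11A.4. The permutation that follows took peaks as independent, so its p may be too small. The absent peaks averaged 81.4% soft-masked bases (SD 29.9) and the kept peaks 24.9% (SD 23.6). The absent peaks were thus higher by 56.5 percentage points (permutation p = 1e-05, the smallest possible). This is consistent with a removal of peaks in repeat or low-complexity sequence before the thresholded lists were made, a step that the file records do not describe. Occurrence in 1 replicate was tested through the share of peaks past the score minimum in both replicates' own ranked lists. As the whole reason for absence, it would make this share lower in the absent than in the kept peaks. The share was 52.7% of the absent peaks (49 of 93, 95% interval 42.1% to 63.1%) and 16.2% of the kept (182 of 1124, 95% interval 14.1% to 18.5%). The difference was 36.5 percentage points (Fisher's exact test, p = 2.04e-14). The absent peaks were also stronger (median signal 125 against 86.3). The shares were not matched on signal, so their difference cannot decide the question. Presence in both lists past the minimum argues against this reason for those 49 peaks. For the other 44 peaks, not passing in both lists cannot alone be the reason, since only 182 of the 1124 kept peaks passed in both. Whether it added to their absence stays open. The interval of the 52.7% includes 50%, so whether most absent peaks passed in both lists is not settled. Presence in both lists at any score decides nothing: the score already selects for it, and it held for 96.8% of the absent and 98.3% of the kept peaks. The design names no biological explanation, and none was tested.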

How the results depend on the processing

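Alternatives numbered 312 over 33 results, and those chosen after seeing the data were the number of peaks in each replicate alone, the limits on IDR of 0.001 and q-value, the inclusion of absent peaks, protein-coding starts, distance from tRNA or snoRNA genes, summits inside gene spans, and matching on biotype or GC content. Among alternatives with a test of their own, without the IDR limit of 0.01 that moves nothing, direction or side of the threshold changed in 12 of 91 for the results that answer a comparison and in 17 of 143 for single classes, lists and biotypes. The number of gene lists called higher was 2 to 4 against 3, and not always the same lists. With the nearest gene start only, up to 1000 bp on either side, chaperones (ratio 5.41 against 6.96) and respiration (6.13 against 5.83) were lost. Cuticle collagens were gained. For summits inside gene spans ribosomal proteins, chaperones (Fisher's exact test, adjusted p = 0.116) and respiration (0.744) were lost and cuticle collagens, heterochronic genes and molting genes gained. Molting genes did not pass against other protein-coding genes with a symbol (5 of 48, Fisher's exact test, adjusted p = 0.0742). Biotypes called higher numbered 4, and 5 with absent peaks included, when rRNA genes were gained (3 bound, ratio 5.45, Fisher's exact test, adjusted p = 0.0231, against 0 of 20). Annotation classes called numbered 3 to 5 against 4, with intergenic sequence lost when absent peaks were included and 3' UTRs gained with the stronger peaks, at an IDR of 0.001 and at a q-value of at most 0.1. The enrichments at tRNA and snoRNA genes and the share at gene starts kept their direction and call under each alternative run. Ratios were 15.1 to 30.9 for tRNA genes and 6.27 to 15.8 for snoRNA genes. Label rotation, which keeps neighbouring genes together, was not run for biotypes. The share at gene starts was not recomputed without peaks near tRNA or snoRNA genes. The number of conservative peaks became 7436 at an IDR of at most 0.1 and 274 at 0.001, and 325 to 337 with either replicate's list alone. The X share turned to 14.8% without peaks near tRNA genes, below X's share of the genome but above its shares of all and of protein-coding gene starts, and not past the test against either. The share in chromosome centres, 49.2% and not past the test, lay above 50% with either replicate's list alone (51.6% to 54.8%), with the stronger peaks (50.5%), at an IDR of 0.001 (52.2%) and at a q-value of at most 0.1 (51.9%), none past the test. With gene starts as background the same 49.2% passed the test in opposite directions for all and for protein-coding starts. The ribosomal protein ratio was 3.64 (Fisher's exact test, adjusted p = 0.1) for summits inside the gene's span, and the sequence ratio 1.59 (Fisher's exact test, p = 0.0609) over 500 bp from tRNA genes with windows matched on GC content. Among annotation classes that did not pass, the direction turned for 5' UTRs with the other series list (0.524%). Noncoding exons held 1.19% to 1.54% with either replicate's list alone, above their 1.43% of the genome without replicate 1 and below it without replicate 2, and 1.46% at an IDR of 0.001. The call of fewer intergenic summits ended with absent peaks included, where the share turned to 13.6% (exact binomial test, adjusted p = 0.588), and 66 of the 93 peaks added were intergenic. The cause of the other changes was not tested. The leading 6-mer was not the same in each setting. Against flanking windows it was ACCACT (AGTGGT), with a ratio of 6.73, and the leading word of 8 bases was AGTGGTTA (TAACCACT), with a ratio of 23.3. Depth is unknown and limits every statement about sites without a peak. No paired analysis was possible because there is 1 group.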

Other observations

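The tests on summits inside gene spans and without peaks near small RNA genes were chosen after the data were seen. Cuticle collagen genes, which encode the worm's exoskeleton, held summits within their spans. Of 175 such genes 30 (17.1%, 95% interval 11.9% to 23.6%) had a summit inside their span, against 2.59% of other protein-coding genes with a symbol (Fisher's exact test, adjusted p = 2.08e-14). Besides col-107, col-19 and col-130 they included col-93 (signal 182) and col-125 (155), while col-39 had a summit in its start window (178) and another in a coding exon (168). The heterochronic genes lin-42, lin-14 and lin-29, which time larval development, were 3 of 9 with a summit in their span (Fisher's exact test, adjusted p = 0.0154). The test takes no account of gene length, and these genes are long (II:1233236-1252359, X:11465560-11485871 and II:11917642-11935343), so their length alone is not excluded. At their starts 1 of 9 was bound (Fisher's exact test, adjusted p = 0.619). Chemoreceptor genes were below other protein-coding genes (11 of 1364, Fisher's exact test, adjusted p = 6.19e-06), a call that was lost against all genes with a symbol (14 bound, ratio 0.593, Fisher's exact test, adjusted p = 0.171). Outside the tRNA class, the RNA genes rpr-1, mrpr-1, srpr-2.1, srpr-2.2 and srpr-3 had summits from 19 to 116 bp inside their starts, while srpr-1.1 and srpr-1.2 were not bound. These RNA genes were singled out after their values were seen.

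That tRNA genes were bound more often than other genes may have technical sources. Reads shared between identical copies would leave tRNA genes with a sequence found only once near the level of other genes. Of these 143 genes 26.6% were bound (95% interval 19.5% to 34.6%), against 2.15% of other genes. Sharing between near-identical copies cannot be judged this way, since only exact copies were set apart. A summit at a neighbouring tRNA gene in the start window also counts as binding. Genes with an identical copy were bound in 52.03% of cases (Fisher's exact test, p = 6.5e-08). How much of the excess comes from shared reads therefore stays open. GC content as the whole source is argued against by 40.3% bound among tRNA genes below the tRNA median of 58.3% GC. This is a weak test, as these are GC-rich too. Another value against it was 7.24% bound (95% interval 6.26% to 8.33%) among 2485 other genes, against 46.1% for tRNA genes. These other genes reached the median GC content of tRNA genes in windows at the start, of the size used at summits. Such windows are shorter than the start window for binding, and summits at bound protein-coding genes had a median offset of -310 bp. GC content where those summits lay was therefore not matched, which limits this comparison. It was chosen after a first run on the data. A general enrichment at highly transcribed loci stays a candidate explanation that these data cannot decide. Ribosomal protein, collagen and histone genes together held summits inside their span 4.38 times as often as other protein-coding genes (37 of 328, 11.3%, against 2.58%, Fisher's exact test, p = 2.56e-13). This test was chosen after the data, with summits in collagen genes, had been seen. It rests on collagens (30 of the 37), so it gives no independent support. Histones held 2 of 72 (2.78%) and ribosomal proteins 5 of 81, neither past the test alone. The test takes no account of gene length, so shares of short and long genes are not directly comparable. Transcription was not measured here, and the control experiment was not analysed.

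Small RNA genes near the same starts could account for the ribosomal protein result, since many snoRNA genes lie in or beside ribosomal protein genes. Without peaks within 500 bp of a snoRNA or tRNA gene, 12 of the 81 ribosomal protein genes were still bound (14.8%, ratio 11.4 to other genes, Fisher's exact test, adjusted p = 2.61e-08), against 14 with all peaks, which argues against this source. The ratio was above the 7.93 of all peaks because the share of other genes fell from 2.18% to 1.3%, so its rise adds no evidence. An enrichment over highly transcribed genes was not excluded. Inside their own spans ribosomal protein genes did not pass against other protein-coding genes with a symbol (5 of 81, ratio 2.28, Fisher's exact test, adjusted p = 0.297). That test cannot decide the question, since the start-window summits of the 14 bound genes lay upstream of their starts. No biological explanation was tested.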
